A study of Ectopseudomonas oleovorans CECT 5344 with 8 samples.

How the data were processed

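RNA of the cyanide-degrading bacterium Pseudomonas pseudoalcaligenes CECT5344 (listed by the labels under its current name, Ectopseudomonas oleovorans) was compared on 8 two-colour Agilent arrays. Each array held 2 RNA samples, 1 labelled with Cy5 and the other with Cy3, so that 16 samples were measured, 4 for each of 4 nitrogen states. Per the labels, the samples of a state were biological replicates, and every array held a different pair of samples. The arrays formed a closed loop in which cyanide was hybridised with ammonium, ammonium with starvation, starvation with wastewater and wastewater with cyanide, each pair of states on 2 arrays with the dyes exchanged. Cyanide and starvation, and likewise wastewater and ammonium, never shared an array.

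Per the file headers and the submitters' processing notes, the arrays were scanned and read with Agilent Feature Extraction 10.7.3.1, each array alone. The deposited scanner files give the intensity of each spot in both dyes and of the background around it, as linear scanner units with no normalization between the dyes. They also hold a log10 ratio of Cy5 over Cy3, which the scanner software computed after its own background subtraction and dye normalization, per the file headers. A deposited table of log2 ratios for the whole series was used as an alternative only. Its columns followed the scanner's ratio of the same array in the same direction (lowest r across spots 0.988, slopes between 0.910 and 0.945), and its medians lay between -0.0163 and 0.0207, so that its scale, direction and centring could be read, while its normalization method is not given in the sources used here. On the first and second array of each pair of states, those medians were 0.0207 and -0.0163 for cyanide and ammonium, 0.00621 and -0.0102 for wastewater and cyanide, -0.0067 and 0.00934 for wastewater and starvation, and 0.00937 and -0.00223 for starvation and ammonium.

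Each array carried 62075 spots, of which 60756 belonged to 4304 genes, usually as 7 different probes with 2 spots each, and 1319 were controls. Background was corrected with normexp (offset 50) on the median signal and the median background, since the files used here hold median and not mean spot signals. Ratios were normalized within each array by loess with controls at weight 0, which sets the median gene of every array near 0. Spots marked as outliers by the scanner software were left out (55 to 90 gene spots per array), and no gene spot was saturated. Spots of a probe were averaged. Probes well above background in at least 3 of the 4 samples of at least 1 nitrogen state were kept (30053 of 30128), and the gene value was the mean over its kept probes. A probe was taken as well above background in a sample where at least 0.5 of its spots were. All 4304 genes stayed in the tests, and none was below background in all samples of a state.

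The log2 ratios of the 8 arrays were fitted in one linear model with a parameter for each state against ammonium and a dye term, using limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). The fit left 4 residual degrees of freedom per gene, to which the moderation added 3.85. All 6 comparisons between states were taken from that fit, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Genes of cyanide, and of wastewater, that differed in the same direction from both ammonium and starvation were counted as 2 intersections. The design, the tests, most alternatives and the rule for naming genes were chosen before the data were examined. Values with ± are standard errors of the fit for log2 changes and SD over 4 samples for signal levels, and the number of arrays limits their precision. Signal levels of single samples were taken after loess and quantile normalization of the mean intensities between arrays.

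The files identify genes by protein accession only and do not pair these with gene names. The gene table of another strain (assembly ASM2981487v1) matched 0 of the 4304 identifiers. The 21 gene lists chosen in advance could therefore not be matched and their tests were not run. The naming rule asked for the largest increases and decreases past the threshold, with the same sign on both arrays for states that shared arrays, among genes with a name. Without names it was applied to all genes and limited to 2 increases and 2 decreases per comparison. Genes are further described by runs, meaning at least 3 consecutive accession numbers that all changed at least 2-fold in the same direction past the threshold. This definition was chosen after seeing the data. Consecutive numbers are taken only as the order of the identifiers, since no genome annotation of this strain was used here.

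The model was tested on simulated data for the real genes and their spread, with 200 genes changed. For cyanide against ammonium it found on average 91.4% of 2-fold and 99.9% of 4-fold changes and called 11.1 unchanged genes, over 10 simulations with 4304 genes. For cyanide against starvation, which shared no array, it found 83.8% of 2-fold and 99.8% of 4-fold changes and called 9.5 unchanged genes, and for wastewater against cyanide 92.3%, 99.9% and 9.7. In the comparison of wastewater with ammonium, left unchanged in the same simulations, it called 0.1 genes on average. The simulated errors were independent between genes and equally wide on all arrays. When each real array was predicted from the others, the SD of the error ranged from 0.35 to 0.73 log2 units. Those errors correlated between consecutive accession numbers with r from 0.24 to 0.45. The simulated rates may therefore be too favourable for the real data.

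Alternatives covered the background correction, the scanner's own ratio, median centring in place of loess, scale normalization between arrays, the dye term, the label replicate numbers as a block, the brightest probe per gene, both looser and stricter filters on dim probes, a separate-channel fit, a trended robust moderation, the deposited table, and each array left out in turn. A block for slide or scan was planned but could not be fitted, because all 8 arrays lay on 1 slide with 1 scan. After seeing the data, centring on the 10 spike-in control probes, a dye term for each of the 2 rows of the slide and fits within a row were added.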

Results

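Gene expression of Pseudomonas pseudoalcaligenes CECT5344, a bacterium that can use cyanide as its nitrogen source, was measured in cultures with different nitrogen supplies. Cells grew at 30 °C in M9 minimal medium on acetate (50 mM), with ammonium (2 mM) as the first nitrogen supply. After 24 h, when ammonium was used up, separate cultures received sodium cyanide, a cyanide-containing wastewater from the jewelry industry or ammonium chloride, each at 2 mM, or received no nitrogen (starvation). Each state had 4 samples. The median gene spot ranged from 495 to 2339 scanner units and the median background from 39 to 113, so the median signal was 7.59 to 33.5 times its background. Between 98.2% and 99.99% of probes were well above background in each sample. Ammonium samples were the brightest, with a mean of the median signal of 1834 ± 366 (SD, n = 4), against 955 ± 142 for cyanide, 837 ± 92.7 for wastewater and 571 ± 87.6 for starvation.

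**Figure D1:**
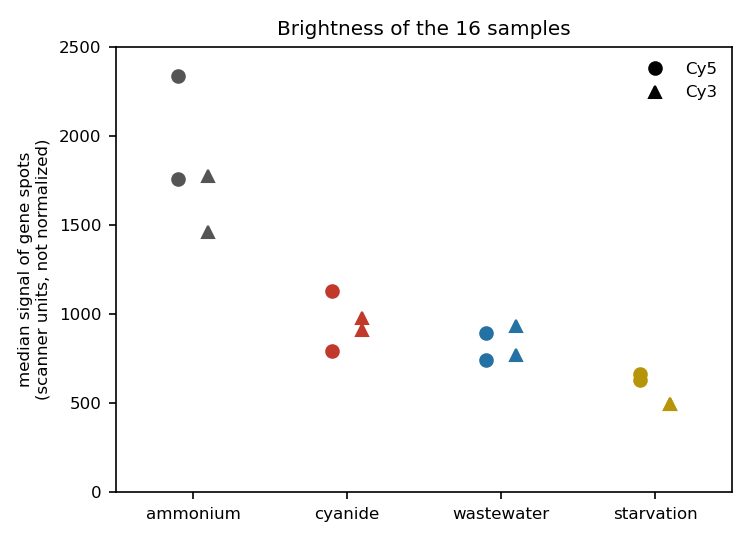
Median signal of all gene spots in each of the 16 samples (vertical axis, scanner units before normalization) by nitrogen state (horizontal axis), with circles for Cy5 and triangles for Cy3. The 4 ammonium samples lie between 1464 and 2339 and the 4 starvation samples between 495 and 662, with both dyes.

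The changes below are relative to the median gene of each array. Against the spike-in control spots, the median gene was lower than in ammonium by a log2 change of -1.18 ± 0.18 in cyanide, -1.46 ± 0.20 in wastewater and -1.86 ± 0.18 in starvation (SE, 8 arrays), so centring on the spike-ins moves every change by these amounts. For that reason the division into higher and lower genes is given with both centrings.

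The first comparison asked how cells supplied with cyanide differ from cells supplied with ammonium. The gene with the largest increase under cyanide, CCH38469.1, was 8.68 ± 0.30 log2 units higher than with ammonium, a 410-fold difference. It lay in a run of 10 genes with consecutive accession numbers whose increases ranged from 1.36 to 8.68. The mean log2 signal of CCH38469.1 in ammonium was 8.06 ± 0.53 (SD, n = 4). Here and below, the size of increases from such low levels depends on the background correction and its offset. CCH38469.1 was also 7.65 ± 0.30 higher in starvation than in ammonium, and between cyanide and starvation it differed by 1.03 ± 0.34 (adjusted p = 0.0619 from limma). That difference varied with the arrays used. It was 1.44 ± 0.21 (adjusted p = 0.00363 from limma) without the array of the fourth cyanide sample, where the log2 signal of the gene was 14.16, against 16.26 to 16.88 in the others. Without any other array it lay between 0.74 and 1.21, with adjusted p from limma between 0.0537 and 0.198. The mean of its run was 6.13 in cyanide and 5.45 in starvation, and with all arrays 2 of the 10 genes passed the threshold between these states. The second largest increase, 8.66 ± 0.29 log2 units for CCH37728.1, lay in the longest run of higher genes, 23 genes with increases between 1.08 and 8.66 and a mean of 5.15. The mean log2 signal of CCH37728.1 was 7.85 ± 0.49 in ammonium and 16.62 ± 0.34 in cyanide (SD, n = 4). Among lower genes, CCH38341.1 changed by -4.99 ± 0.70 and CCH40222.1 by -4.03 ± 0.27. The adjusted p values of these 4 genes from limma lay between 7.74e-07 and 0.00125, and both shared arrays and all 7 probes of each gene had the same sign. For CCH38341.1, the cyanide samples spread most, at 8.84 ± 1.51. Here too the fourth cyanide sample lay apart, at 11.04, against 7.63 to 8.45 in the others.

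In total 1912 of 4304 genes changed between cyanide and ammonium, 992 higher and 920 lower, and 730 of them at least 2-fold. With spike-in centring, 122 genes were higher and 3510 lower, and scale normalization between arrays called 920 genes. Of the genes changed at least 2-fold, 295 lay in 63 runs, and the longest run of lower genes held 15, with changes from -1.78 to -1.01. Without the first of the 2 arrays that shared cyanide and ammonium the count was 947.

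Wastewater and ammonium never shared an array, and their comparison rests on the paths through cyanide and through starvation. The 2 paths have no sample in common, and their log2 changes correlated across genes with r = 0.85 (genes are not independent replicates). The rank correlation was 0.71. The largest increase of the 6 comparisons was found here. CCH36561.1 was 11.29 ± 0.40 log2 units higher in wastewater, with a mean log2 signal of 6.90 ± 0.54 in ammonium and 17.21 ± 0.10 in wastewater (SD, n = 4). It was also higher than with ammonium in cyanide, by 6.13 ± 0.34, and in starvation, by 5.83 ± 0.34. CCH38474.1, in the run of 10 genes that also held the gene with the largest increase under cyanide, rose by 10.92 ± 0.35, against 8.66 ± 0.30 in cyanide and 7.60 ± 0.30 in starvation. The longest run of higher genes had 24 members with a mean of 4.84 and covered the run of 23 found under cyanide. The 2 largest decreases were those of CCH40222.1, at -4.48 ± 0.31, and of CCH40252.1, at -4.11 ± 0.24. CCH40252.1 also fell in cyanide, by -3.77 ± 0.21, and in starvation, by -3.41 ± 0.21. Adjusted p values from limma for the 4 named genes lay between 1.20e-06 and 3.71e-05.

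In total 1877 genes changed between wastewater and ammonium, 962 higher and 915 lower, and 905 at least 2-fold. With spike-in centring, 125 were higher and 3622 lower, and scale normalization between arrays called 911 genes. Runs held 376 of the genes changed at least 2-fold.

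Starvation against ammonium, a comparison of cells with and without nitrogen, gave the highest count of the 6. CCH37520.1 was 8.39 ± 0.20 log2 units higher in starvation and CCH37164.1 was 8.01 ± 0.36 higher. The run around CCH37520.1 had 6 genes with increases between 2.76 and 8.39. All 6 rose in wastewater too, with a mean of 5.14 log2 units, whereas 2 of the 6 passed the threshold in cyanide, where their mean was 0.29. The largest decreases were in CCH40433.1, at -4.32 ± 0.21, and CCH40434.1, at -4.20 ± 0.32, neighbours in a run of 8 lower genes with a mean of -3.59. The adjusted p values from limma for these 4 genes lay between 3.09e-07 and 3.17e-05. The longest run of the comparison held 38 lower genes with changes from -3.66 to -1.50 and a mean of -2.67. The means of these 38 genes were -0.93 in cyanide and -0.97 in wastewater.

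In total 2528 genes changed between starvation and ammonium, 1274 higher and 1254 lower, and 1196 at least 2-fold. With spike-in centring, 102 were higher and 3929 lower. Runs held 515 of the genes changed at least 2-fold, in 111 runs.

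**Figure D2:**
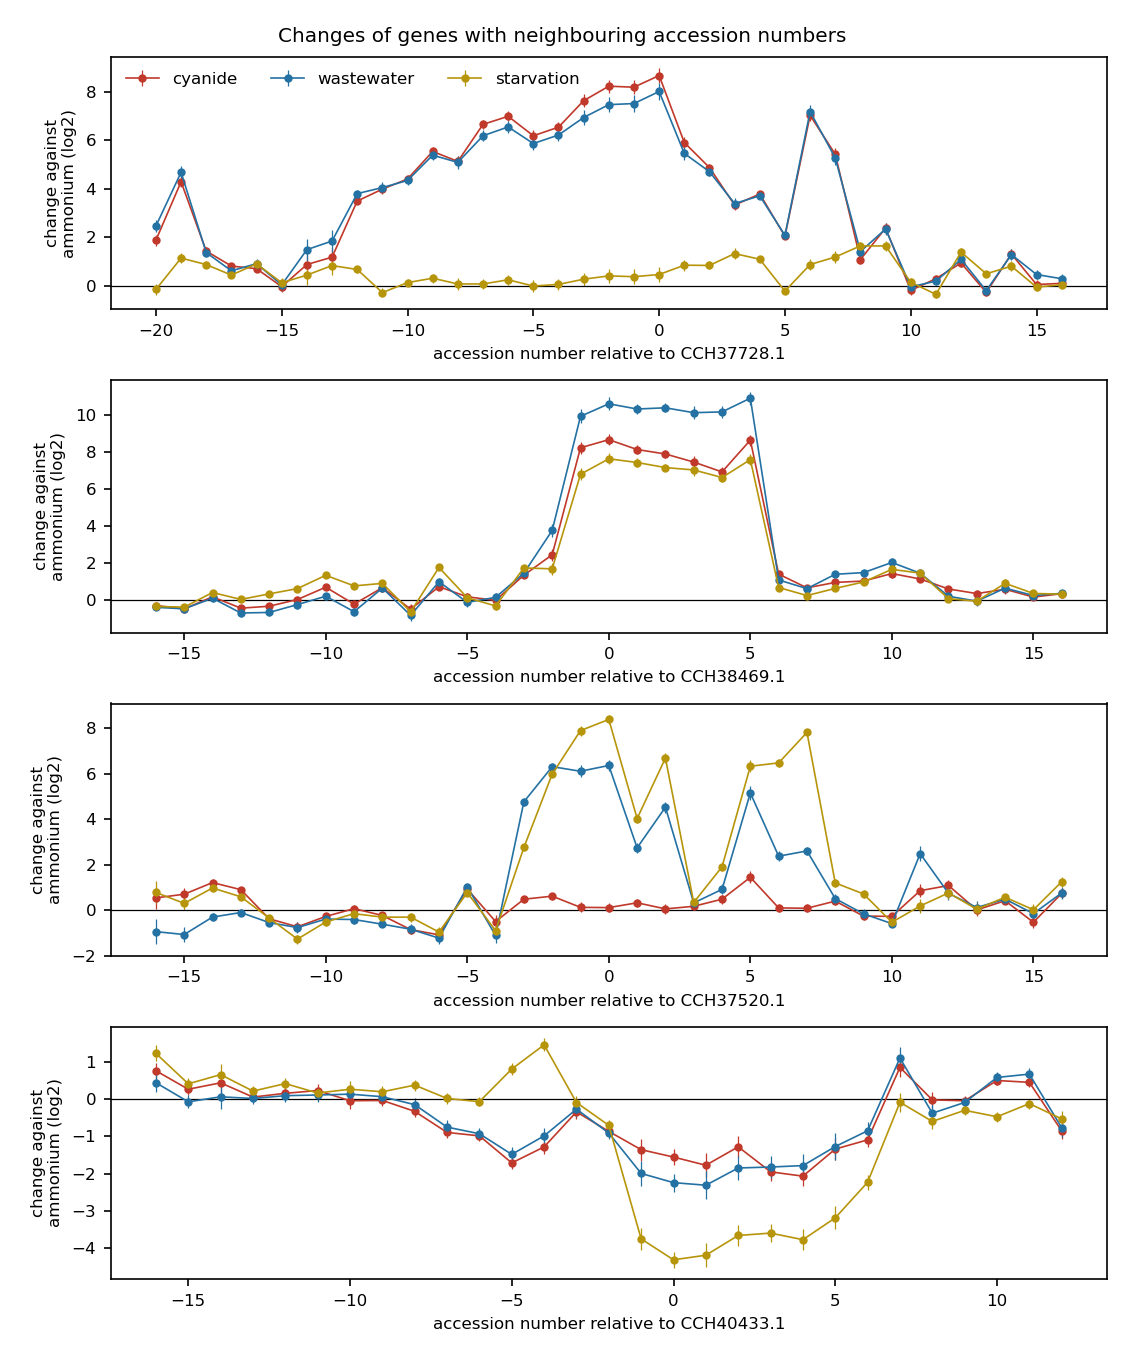
Log2 change against ammonium (vertical axes) of genes in the order of their accession numbers (horizontal axes, counted from the gene named under each panel) for cyanide, wastewater and starvation, with bars for SE. The top panel shows the run higher in cyanide and wastewater (means 5.15 and 4.99) with a mean of 0.55 in starvation, and the lowest panel shows the run of 8 genes lowest in starvation (mean -3.59).

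Cyanide was compared with starvation to separate cells given cyanide from cells given no nitrogen. These states never shared an array. CCH37728.1 was 8.20 ± 0.34 log2 units higher in cyanide and CCH37726.1 was 7.82 ± 0.32 higher, both in a run of 20 higher genes with a mean of 5.26. CCH37520.1 and its neighbour CCH37519.1 were lower in cyanide, by -8.28 ± 0.23 and -7.78 ± 0.25. Adjusted p values from limma for the 4 genes lay between 7.07e-07 and 2.58e-06. The longest run held 25 genes that were higher in cyanide, with a mean of 1.81. These genes were lower than in ammonium in both states, with means of -0.91 in cyanide and -2.72 in starvation, and 19 of the 25 passed the threshold for cyanide against ammonium.

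In total 1109 genes changed between cyanide and starvation, 636 higher and 473 lower in cyanide, and 619 at least 2-fold. With spike-in centring, 1835 were higher and 143 lower. The count was 739 without the first array of cyanide and ammonium, 734 without the first of wastewater and starvation, 718 without the first of starvation and ammonium, 710 with scale normalization between arrays, and 2351 in a separate-channel fit. Between arrays, the separate-channel fit cannot tell these states from the slide row, since each of them lay in a single row.

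**Figure D3:**
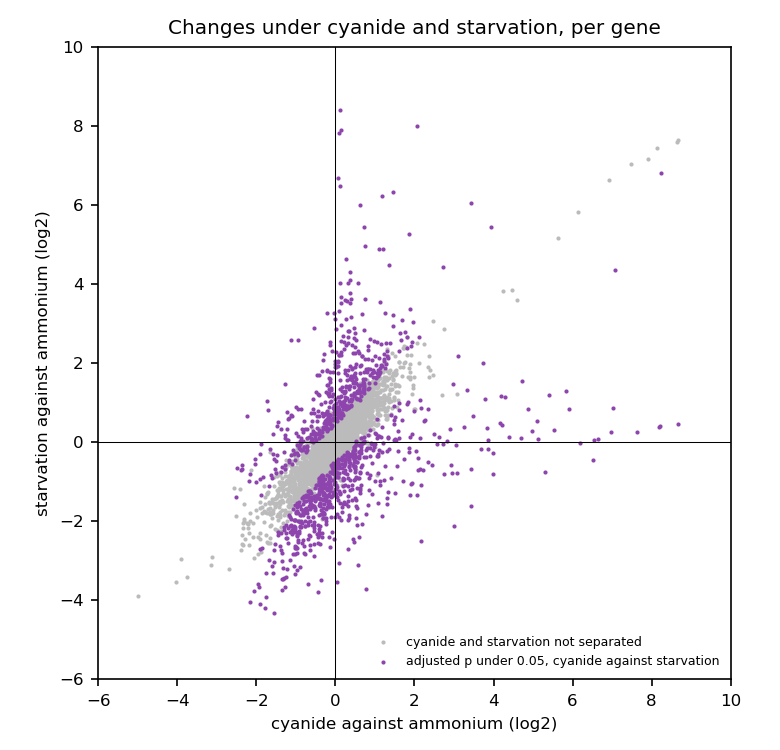
Each point is 1 of 4304 genes, with its log2 change in cyanide against ammonium (horizontal axis) and in starvation against ammonium (vertical axis). The 1109 genes past the threshold between cyanide and starvation are purple, and the others are grey.

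For wastewater against starvation, CCH37728.1 and CCH37727.1 had the largest increases, 7.54 ± 0.29 and 7.14 ± 0.30 log2 units, in a run of 20 higher genes with a mean of 5.02. The arrays that shared these states gave 8.00 and 6.65 for CCH37728.1 and 7.72 and 6.03 for CCH37727.1. The lower values came from the array with the first starvation sample, which was the brightest starvation sample for both genes. Without that array the increases were 7.97 and 7.71. The largest decreases were -5.21 ± 0.17 for CCH37527.1 and -4.10 ± 0.18 for CCH37526.1. Both genes were nonetheless higher in wastewater than in ammonium, by 2.61 ± 0.20 and 2.38 ± 0.21. The adjusted p values from limma of the 4 genes lay between 2.29e-06 and 4.07e-06. The longest run of any comparison held 41 genes that were 1.18 to 2.16 log2 units higher in wastewater than in starvation. Being higher than in starvation need not mean a rise over ammonium. The 38 genes of the longest run in starvation against ammonium all passed the threshold here too, with a mean of 1.70. Against ammonium, the means of those 38 genes were -0.97 in wastewater and -2.67 in starvation.

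In total 1374 genes changed between wastewater and starvation, 772 higher and 602 lower in wastewater, and 619 at least 2-fold. With spike-in centring, 1245 were higher and 221 lower. The count was 651 without the first array that shared these states, and 2254 in a separate-channel fit.

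Wastewater and cyanide differed least. CCH37520.1 and CCH37519.1 were higher in wastewater by 6.25 ± 0.20 and 5.99 ± 0.22 log2 units, and all 6 genes of their run passed the threshold with a mean of 4.85. CCH36880.1 and CCH36879.1 were lower in wastewater by -4.99 ± 0.18 and -4.68 ± 0.25, in a run of 4 genes with a mean of -4.01. The mean log2 signal of CCH36880.1 was 13.79 ± 0.39 in cyanide, 8.87 ± 0.18 in wastewater, 8.44 ± 0.17 in ammonium and 7.74 ± 0.08 in starvation (SD, n = 4). Adjusted p values from limma for the 4 genes lay between 3.08e-06 and 1.69e-05. None of the 23 genes in the long run higher in cyanide than in ammonium passed the threshold between wastewater and cyanide, where their mean difference was -0.17.

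In total 401 genes changed between wastewater and cyanide, 194 higher and 207 lower in wastewater, and 236 at least 2-fold. With spike-in centring, 90 were higher and 291 lower. The count was 224 without the first and 262 without the second of the arrays that shared these states, 252 with median centring in place of loess, and 786 in a separate-channel fit. Across genes, the log2 changes on the 2 arrays that shared these states correlated with r = 0.67 (rank correlation 0.32).

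Genes that set cyanide apart from both cyanide-free states numbered 316, with 205 higher and 111 lower. The smaller of the 2 changes was largest in CCH37728.1 and CCH37726.1, at 8.20 and 7.82 log2 units, both in comparison with starvation. Among lower genes it was -2.23 ± 0.25 in CCH38130.1 and -1.83 ± 0.18 in CCH40306.1. CCH40306.1 moved the other way in wastewater, where it was 1.19 ± 0.18 higher than in ammonium and 1.84 ± 0.16 higher than in starvation. With spike-in centring 91 genes were higher and 115 lower. The count was 171 without the first array of cyanide and ammonium, 197 without the first of starvation and ammonium, and 578 in a separate-channel fit (310 higher and 268 lower).

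Genes that set wastewater apart from both cyanide-free states numbered 444, with 264 higher and 180 lower. CCH37728.1 and CCH37727.1 again had the largest smaller change, 7.54 and 7.14 log2 units. Among lower genes it was -3.25 ± 0.31 in CCH36857.1 and -3.10 ± 0.34 in CCH38746.1. With spike-in centring 98 genes were higher and 167 lower. The count was 265 without the first array of wastewater and starvation, and 707 in a separate-channel fit (335 higher and 372 lower).

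**Figure D4:**
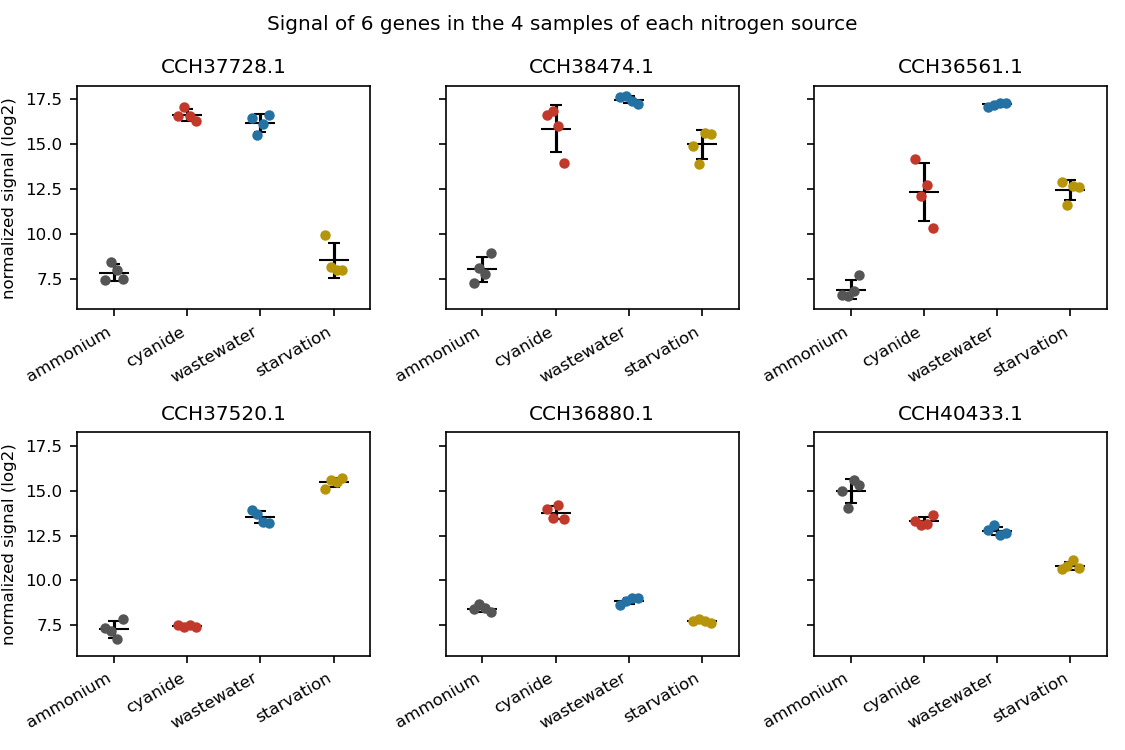
Normalized log2 signal (vertical axes) of 6 genes in the 4 samples of each nitrogen state (horizontal axes), with points for samples, and mean and SD as black bars. CCH36561.1 has a mean of 17.21 in wastewater and 12.33 in cyanide, where its 4 samples spread widely (SD 1.59). CCH36880.1 has a mean of 13.79 in cyanide and 8.87 in wastewater.

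The profiles over the 4 states were then counted, each gene being taken only where every comparison named passed the threshold in the stated direction. In all 3 states without ammonium, 609 genes were higher and 577 lower than with ammonium, and with spike-in centring 24 were higher and 3303 lower. The near-even division thus depends on the centring, and the 24 and 577 genes of the smaller counts were contained in the larger ones. These comparisons share the ammonium samples. With no effect, simulation gave a mean of 0 such genes. It made at most 4 calls in a simulation, so it cannot show how far the shared samples raise the overlap of called genes. Independent lists would share 65.6 higher and 57.0 lower genes. The fits within each slide row, with 1 residual degree of freedom each, gave separate ammonium samples for cyanide and starvation. In them, 619 higher and 652 lower genes were called in both comparisons, against 278 and 277 for independent lists. With the shared samples these 2 comparisons had 721 higher and 720 lower genes in common, against 294 and 268. With spike-in centring they had 31 higher and 3389 lower genes in common, against 2.89 and 3204 for independent lists, and with separate ammonium samples 33 and 3094, against 3.89 and 3005. Across genes, their log2 changes correlated with r = 0.60 (covariance 0.694), against 0.33 (covariance 0.0131) in simulation with no effect, and with r = 0.53 (covariance 0.644) on separate ammonium samples.

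Cyanide and wastewater were both higher than both cyanide-free states for 115 genes and both lower for 57. With spike-in centring the counts were 57 and 61, of which 47 and 17 were the same genes. Among the 115 genes the median change against ammonium was 2.04 log2 units in cyanide, 1.84 in wastewater and 0.03 in starvation. Starvation stood apart from each of the other 3 states for 284 higher and 379 lower genes (56 and 1086 with spike-in centring, which hold 56 and 379 of the same genes). Wastewater and starvation were both higher than ammonium and cyanide for 78 genes and both lower for 56 (17 and 204 with spike-in centring, of which 17 and 49 are the same genes). Cyanide alone stood apart from the other 3 states for 57 higher and 13 lower genes, and wastewater alone for 94 higher and 77 lower genes. With spike-in centring, cyanide alone stood apart for 25 higher and 20 lower genes, of which 22 and 3 were the same genes, and wastewater alone for 36 and 77, of which 35 and 65 were the same. The 13 lower genes of cyanide alone thus mostly depend on the centring.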

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

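The carry-over and channel tests of the starvation sample, the dye test of the spike-in shift and the shuffled gene order were chosen after the results were seen. The test of the amount of labelled RNA was also chosen then, and its failing outcome was reworded once its value was known. The brightness limit of the carry-over test was first set higher, which left a single gene outside the run, and was lowered to 16-fold after that was seen. The other tests were chosen before.

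In 100 splits of the 16 samples into 4 states, the real one included, as many genes as in the real split were called by 1 split for cyanide against ammonium (1912 genes, highest other split 1729), by 1 for wastewater against ammonium (1877, other 1330), by 1 for starvation against ammonium (2528, other 1461), by 2 for cyanide against starvation (1109, other 1256), by 2 for wastewater against starvation (1374, other 1683), and by 1 for wastewater against cyanide (401, other 203). For the genes apart from both cyanide-free states it was 3 splits for cyanide (316, other 931) and 1 for wastewater (444, other 6). At most 3 of the 100 splits, the real one included, thus reached any of the counts. The other splits were not held to the balanced, dye-swapped loop of the real one. They therefore cannot exclude chance as the origin of a count. Why another split called 931 genes was not tested.

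Spike-in spots, which the model centred on the median gene does not use, stood out against the genes. Relative to them the median gene changed by -1.18 in cyanide, -1.46 in wastewater and -1.86 in starvation against ammonium (log2). A dye or scanner effect would have turned with the dyes, but the ammonium channel was brighter on all 4 of its arrays, by at least 0.96 log2 units, where the spike-in offsets had an SD of 0.16. At least 80.6% of genes were brighter in ammonium on each of those arrays, so the shift was not confined to a few genes. This cannot exclude a few abundant genes as its origin, since a larger share for them in the other states would also lower most other genes. The mean shift was 1.52 log2 units, and a difference in the amount of labelled RNA, in labelling yield or in the messenger share of total RNA may underlie it. These cannot be told apart, because nothing but the spike-ins measures the input.

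Of 100 sets of 4 samples checked, 6 had a sample far from the other 3, where chance gives about 5. The log2 signal of CCH40306.1 was 13.92 in the third wastewater sample, against 13.65 to 13.67 in the others, and that of CCH36857.1 was 13.46 in the second ammonium sample, against 14.01 to 14.12. In the first ammonium sample CCH37726.1 was at 8.32, against 9.28 to 9.45.

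The other 3 lay in the first starvation sample and in the run of 23 genes higher in cyanide: 9.97 for CCH37728.1 (others 7.98 to 8.14), 11.03 for CCH37726.1 (9.27 to 9.56) and 10.93 for CCH37727.1 (8.95 to 9.17). Single defective spots are argued against, since this sample was the brightest of the 4 in 20 of the 23 genes. Its excess was a median of 1.54% of the signal of the wastewater sample on the same array over 16 genes of the run at least 16-fold brighter there, and 1.59% over 15 such genes outside it, which is consistent with carry-over of wastewater RNA or signal. Cy3 signal read in the Cy5 channel would also have raised the third cyanide sample, in Cy5 beside wastewater in Cy3, where the median excess was -0.00274%. A weak response of that culture stays open, and no biological explanation was tested.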

How the results depend on the processing

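Centring on the spike-ins, the dye term per slide row and the fits within a row were chosen after seeing the data. All 32 changes of named genes kept their direction and stayed past the threshold under every alternative run. These genes were picked for the largest changes in the same fit, so this says little about a typical called gene. The median absolute change of called genes was 0.85 to 1.16 log2 units over the 6 comparisons. Counts left the range of 1.5 times as follows, and the cause was not tested except where given. Scale normalization between arrays called 920 genes for cyanide against ammonium, 911 for wastewater against ammonium and 710 for cyanide against starvation, and median centring called 252 for wastewater against cyanide. A separate-channel fit, which also uses the comparison between arrays, called 2351 for cyanide and 2254 for wastewater against starvation, and 786 for wastewater against cyanide. For cyanide and wastewater apart from both cyanide-free states it called 578 and 707 genes. All cyanide samples lay in slide row 2 and all starvation samples in slide row 1. That fit has no term for the row, so between arrays it cannot tell these 2 states from the rows. Spike-in centring moves every gene alike and called 3632, 3747 and 4031 genes for cyanide, wastewater and starvation against ammonium, 1978 for cyanide against starvation, and 206 and 265 for the 2 intersections.

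Leaving out 1 array gave 947 to 2012 genes for cyanide, 1316 to 1831 for wastewater and 1738 to 2678 for starvation against ammonium, 718 to 1283 for cyanide and 651 to 1631 for wastewater against starvation, 224 to 554 for wastewater against cyanide, and 171 to 359 and 265 to 464 for the intersections of cyanide and wastewater.

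The replicate numbers as a block left 2 residual degrees of freedom and called 1850, 1885 and 2192 genes against ammonium (cyanide, wastewater, starvation), 770 and 1244 against starvation (cyanide, wastewater), 334 for wastewater against cyanide, and 309 and 486 for the intersections. It changed no call of a named gene. Deviations of same-numbered samples of different states on different arrays correlated across genes with r between -0.454 and 0.347, above 0.1 in 7 of 20 pairs. For differently numbered samples r lay between -0.430 and 0.459, above 0.1 in 26 of 68 pairs. Same-numbered samples thus did not deviate together more than others, and the numbers were not taken to pair the samples. This does not exclude a pairing. With a dye term per slide row the counts were 1721, 1701, 2376, 993, 1192, 333, 280 and 385 in the same order. Within a row they were 1705 for cyanide and 2803 for starvation against ammonium, 1845 and 1366 for wastewater against ammonium, 1967 for wastewater against starvation, 356 for wastewater against cyanide, and 551 for wastewater apart from both cyanide-free states. Cyanide and starvation shared no row, and each fit within a row left 1 residual degree of freedom. The slide or scan block and the tests of gene lists were not run.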

Other observations

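The shuffled gene order was tested after the runs were seen, and the test of array position was chosen before its result was known.

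Other runs, not tied to a named gene, had profiles of their own. In cyanide against ammonium, a run of 10 genes was higher by a mean of 2.64 log2 units, with means of 2.20 in wastewater and -1.14 in starvation. A run of 8 genes was lower in wastewater than in cyanide by a mean of -1.41, with means against ammonium of 2.34 in cyanide, 0.93 in wastewater and -0.19 in starvation. In starvation, a run of 13 genes was higher than in ammonium by a mean of 2.04, with 0.53 in cyanide and 1.11 in wastewater. A run of 6 genes was higher in starvation by a mean of 4.76, and 5 of the 6 also passed the threshold in wastewater and in cyanide, where the means over all 6 were 2.31 and 1.88. In wastewater, 16 consecutive genes were higher than in ammonium by a mean of 2.14, of which 15 also differed from cyanide. Their means against ammonium were 0.45 in cyanide and 1.47 in starvation, where 15 of the 16 passed the threshold. Another 9 consecutive genes were lower in wastewater by a mean of -3.07. They were also lower in cyanide (mean -2.00, 8 of 9 past the threshold) and in starvation (mean -2.28, 9 of 9).

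The runs took 40.4% to 54.4% of the genes changed at least 2-fold in the 6 comparisons. In 1000 shuffled gene orders the longest run of any comparison was 8, while the shortest of the 6 longest real runs, in wastewater against cyanide, was also 8 against 4 in its own shuffles (permutation p = 0.001 in each comparison, the smallest that 1000 shuffles can give). Position on the array is argued against, since fold changes of neighbouring spots of unrelated numbers correlated with r of at most 0.00639, while those of consecutive accession numbers correlated with r between 0.55 and 0.64. Genes transcribed together may account for the runs, as a hypothesis that a genome annotation of this strain would test.

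Each array was also predicted from the other 7. The second array of cyanide and ammonium was first weighed as a pattern of its own and then, after its tests were seen, kept as plain values only. The SD of the error was largest for the second array of cyanide and ammonium, at 0.73 log2 units, and smallest for the first, at 0.35. On the second, the errors correlated between consecutive accession numbers with r = 0.45 and between neighbouring spots with r = 0.01. This was not particular to that array. On the others, r lay between 0.24 and 0.44 for consecutive numbers and between 0.007 and 0.015 for neighbouring spots. Around the loop, the 4 direct differences summed to within 1 log2 unit of 0 in 86.5% of genes.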
